A study of Rattus norvegicus with 18 samples.

How the data were processed

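Neonatal rat ventricular myocytes, beating heart muscle cells cultured from the ventricles of 2-day-old Sprague-Dawley pups, were given vehicle or SR9009 for 24 h and then phenylephrine for 0, 4 or 48 h. SR9009 is a synthetic agonist of the nuclear receptors REV-ERBα and REV-ERBβ (genes Nr1d1 and Nr1d2), which repress transcription. Phenylephrine (PE) activates α1-adrenergic receptors and is widely used to make cultured cardiomyocytes hypertrophic. RNA was sequenced from 18 libraries in 6 groups of 3, prepared with a stranded mRNA kit, per the labels' protocols. Groups were taken from the sample titles, which also carry the replicate numbers 0, 1 and 2.

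The deposited table gives FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library) for 17312 genes, per the file headers. It holds 1 FPKM per gene and group, made by the authors from the 3 libraries of each group, with a lower and an upper confidence bound, a status and a locus. The level of confidence and the scaling between libraries are not given in the sources used here. FastQC, Trim Galore, TopHat, Cuffdiff and the rat genome build rn6 are named per the submitters' processing notes, with no versions. Values per library were not used here. No standard deviation, p-value or test between groups could therefore be computed, and the spread between the 3 libraries enters only as far as the authors' bounds carry it. Depth is unknown. The FPKM of all genes summed to between 609018 (vehicle, 0 h) and 710198 (vehicle, 48 h). For genes of at least 5 FPKM, the median half-width of the authors' bounds was between 14.8% and 15.0% of the value in the 6 groups.

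Between 1804 (vehicle, 0 h) and 3485 (vehicle, 4 h) genes were listed at 0 in a group, and 1198 genes in all 6. Because a listed 0 can be a failed estimate, no difference was computed against one. Between 3 and 8 genes per group carried the status HIDATA (too many fragments for an estimate). These included Myh6 and Myh7, whose values in those groups were treated as missing. Another 172 gene and group values lay outside their own bounds and entered no count. Gene symbols were used as the table gives them. Loci are those of the table, written with the first base counted as 1, on rn6. The start was read as counted from 0, because the gene lengths then equal those of the same symbols in a RefSeq gene table of assembly GRCr8 for 2074 genes, against 277 otherwise. Nothing else was taken from that gene table.

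The tests planned before the data were examined (limma on log2 values, camera and fry for gene lists, permutation of pretreatment labels) need values per library and were not run. In their place a rule of size was used, chosen after the form of the table was seen; it is a description and not a test. Values were taken as log2(FPKM + 1), which understates differences of low genes. The 10545 genes with a mean of at least 1 FPKM over the groups were used. A gene was counted as higher or lower when its difference was at least 1 on the log2 scale (2-fold) and the widest range that the authors' bounds allow excluded 0. The interaction of SR9009 with PE is the PE difference in the SR9009 arm minus that in the vehicle arm, by the same rule. The rule was tested on simulated data for the 4 h PE comparison in vehicle over 10385 genes. It recovered 98% and 88% of genes moved by 2 and -2 on the log2 scale, 74% and 76% of those moved by 1.2 and -1.2, and 0% of unmoved genes. For the 4 h interaction it recovered 32% of genes moved by -1. The simulation drew its error from the authors' bounds, so it covers no variation beyond them. Their half-width was taken as 2 standard deviations, an assumption, because their level of confidence is not given.

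Opposition of the PE response was measured on genes that met the rule for the PE difference averaged over both arms. The percent of them whose interaction had the opposite sign is 50 with no effect, if errors are independent and alike in all groups. Its range came from 20 simulations without an effect, which drew errors in that way, with their size taken from the bounds under the same assumption. Errors shared by many genes of a group could move the percent beyond that range. For 25 gene lists fixed before the data were examined (17 pathways and 8 cell types), members that met the rule were counted. The list's median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these values. The erythroid list had 3 of 7 genes measured and was left out. Genes named in the text follow a rule fixed beforehand, with the size rule in place of the test. They are the 8 largest differences per direction among genes that met the size rule, with a symbol that is not a placeholder and at least 5 FPKM in a compared group. Added to these are up to 4 members of each pathway list with at least 3 members meeting the size rule, and always Nppa, Nppb, Acta1, Myh7, Myh6, Nr1d1, Nr1d2 and Arntl. Cell type markers and further list members are given as examples of their list. The part of the rule on overlap between libraries could not be applied, and some genes that the rule selects are not reported here.

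Alternatives were another pseudocount (0.1), no filter on low values or a mean of at least 5 FPKM, quantile normalization, median centring and other selections for opposition. Added after the data were seen were a 1.5-fold size rule, the size rule without the bounds, leaving out small and ribosomal RNA genes, and FPKM rescaled to equal sums. Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.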

Results

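The data describe messenger RNA levels in cultured neonatal rat ventricular myocytes before and after a hypertrophic stimulus, with and without a REV-ERB agonist. Cells received vehicle or SR9009 for 24 h, and RNA was taken at 0 h or after 4 or 48 h of phenylephrine (PE). Each of the 6 groups had 3 libraries, which the authors combined into 1 FPKM per gene and group, so no group value has a standard deviation here and no difference was tested. Differences are of log2(FPKM + 1), and the range in parentheses is the widest that the authors' confidence bounds allow. A gene is called higher or lower when the difference is at least 1 and that range excludes 0. The samples hold no culture at 4 or 48 h without PE, so time in culture and PE cannot be separated within an arm at either time.

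The first comparison set 4 h of PE against 0 h in vehicle-treated myocytes. Transcripts of the natriuretic peptides and of sarcomere-associated hypertrophy genes were higher. Nppb, which encodes brain natriuretic peptide (chromosome 5, 164796229 to 164797531, rn6), had 105 FPKM at 0 h and 1208 at 4 h, a difference of 3.51 (3.11 to 3.91). Nppa, encoding atrial natriuretic peptide (chromosome 5, 164808407 to 164809716), went from 184 to 716 FPKM, and skeletal α-actin Acta1 from 387 to 1536. Of 16 measured hypertrophy-associated genes, 11 were higher and 0 lower, among them Fhl1 at 2.82 (2.40 to 3.24) and the calcineurin regulator Rcan1 at 2.46 (2.02 to 2.89). Among 28 immediate early genes 8 were higher and 0 lower, led by the nuclear receptors Nr4a3 at 3.46 and Nr4a1 at 3.32, with Fos at 2.33. The largest differences of all named genes were in the bradykinin receptor Bdkrb2, with 0.759 FPKM at 0 h and 42.9 at 4 h, the small GTPase Rnd1 at 3.78 and the kinase Sik1 at 3.77. Ch25h at 3.14 and the sphingosine receptor S1pr1 at 3.13 completed the upper end.

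Ribosome biogenesis genes were higher at 4 h in 9 of 18 cases and lower in 0, with a list median of 0.94. Gnl3 differed by 1.30, Nolc1 by 1.27, Nop58 by 1.24 and Wdr43 by 1.22. Of 13 inflammatory genes 3 were higher, Ccl2 by 1.52, Ccl7 by 1.42 and Cxcl1 by 1.21, and 0 were lower. Of 22 sterol and lipid synthesis genes 3 were higher and 0 lower, among them Idi1 at 1.10, which was at 0.98 with quantile normalization and 0.91 with FPKM rescaled to equal sums. Genes of the unfolded protein and amino acid stress response were lower in 4 of 17 cases: Dnajb9 by -1.30, Herpud1 by -1.27, Sdf2l1 by -1.14 and Trib3 by -1.11. The clock output genes Dbp at -1.34, Tef at -1.17 and Per3 at -1.06 were lower, out of 10. In the extracellular matrix list of 23 genes, Tgfb2 at 1.33 and Ctgf at 1.22 were higher while elastin (Eln, -2.22) and periostin (Postn, -1.11) were among 3 lower. With quantile normalization Per3 (-0.997) and Ctgf (0.974) fell just short of the rule. Lower at this time were also Gabrb2 (-2.55), Wisp2 (-2.50), Cxcr4 (-2.41), Igfbp2 (-2.32), Kcne4 (-2.25), Col4a3 (-2.24) and Ccng2 (-2.10). Among cell type markers, the median of 10 fibroblast markers was -0.50, with none meeting the rule, that of 9 smooth muscle markers -0.53, with 1 higher, and that of 10 cardiomyocyte markers 0.48, with Actc1 meeting the rule at 1.85. In total 529 genes met the rule, 287 higher and 242 lower. The split depends on the scaling: with FPKM rescaled to equal sums it was 206 higher and 487 lower. That rescaling moved the median difference of all genes from -0.02 to -0.20 here, from 0.01 to -0.20 for 48 h of PE in vehicle, and from -0.057 to -0.18 for 4 h of PE with SR9009. It moved it from -0.044 to 0.056 for SR9009 at 48 h and from -0.032 to 0.073 for the interaction at 48 h, and by less than 0.1 in the other comparisons.

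**Figure D1:**
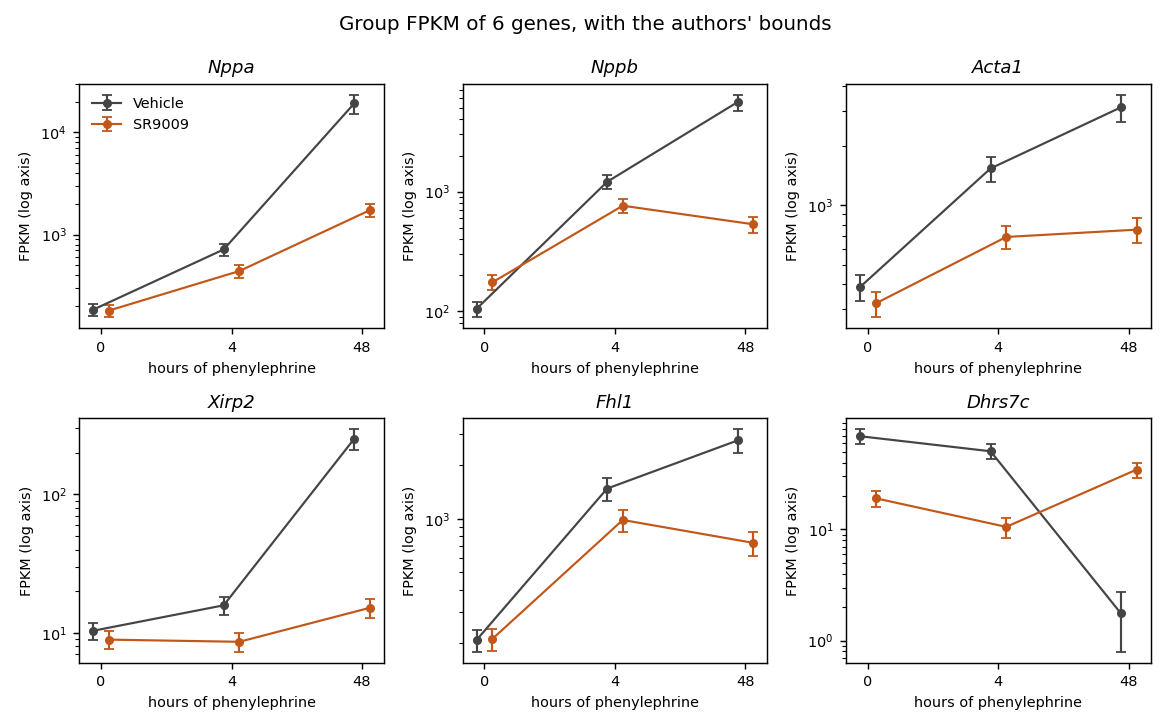
FPKM (log axis) of 6 genes at 0, 4 and 48 h of phenylephrine, with times spaced evenly, in the vehicle and SR9009 arms. Points are the authors' group values and bars their confidence bounds; Nppa reached 19205 FPKM in vehicle and 1734 with SR9009 at 48 h, while Dhrs7c was at 1.76 and 34.6.

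After 48 h of PE in vehicle, the natriuretic peptides had the largest differences. Nppa stood at 19205 FPKM, a difference from 0 h of 6.69 (6.15 to 7.20), and Nppb at 5588 FPKM, a difference of 5.71 (5.29 to 6.14). The hypertrophy list had 11 of 15 members higher and 0 lower, with a median of 2.22. It included the actin-binding sarcomere gene Xirp2 at 4.47 (4.03 to 4.90), Fhl1 at 3.72 and Acta1 at 3.01 (2.57 to 3.45). Outside the list the sodium channel subunit Scn3b (3.81), the skeletal calsequestrin Casq1 (3.80), Bdkrb2 (4.26) and Rnd1 (3.78) were highest. Cholesterol synthesis was the group with the largest share of members higher: 17 of 22 sterol and lipid synthesis genes were higher and 0 lower. Scd1, the stearoyl-CoA desaturase, went from 8.41 to 85.4 FPKM, and Fdps (2.86) and Idi1 (2.56) followed. Of 28 cell cycle genes 13 were higher and 0 lower, led by the ribonucleotide reductase subunit Rrm2 at 2.20 and topoisomerase Top2a at 1.84, with Kif11 at 1.30 and Cenpf at 1.27.

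The mature contractile and calcium-handling list was evenly split at 48 h, with 2 of 18 genes higher, 2 lower and a median of -0.06. The sarcoplasmic calcium pump Atp2a2 was lower by -1.38 (-1.91 to -0.83) and the calcium-binding protein gene Hrc by -1.22, while Actc1 (2.13) and Myl2 (1.22) were higher. Fatty acid oxidation genes had 3 of 19 lower and 0 higher: Acaa2 at 34.6 FPKM against 80.9 at 0 h, the fatty acid transporter Cd36 at -1.03 and Cpt1a at -1.01. Glycolysis genes had 4 of 18 higher, including the phosphofructokinase genes Pfkp (2.21) and Pfkl (1.47) and Pgam1 (1.26), and 1 lower, the muscle isoform Pfkm (-1.13). Immediate early genes were higher in 8 of 28 cases and lower in 0, with Atf3 at 2.52, Dusp4 at 2.24, and Ier3 and Nr4a3 both at 1.51. Ptgs2 (1.75), Ccl20 (1.52) and Lif (1.18) of the inflammatory list were higher and Cxcl1 (-1.01) lower. With quantile normalization Myl2 (0.67) and Cxcl1 (-0.79) no longer met the rule. Nor did Lif with FPKM rescaled to equal sums, at 1.04, where its range no longer excluded 0. The matrix list was split, with Tgfb2 (2.05) and Ctgf (1.70) among 4 higher and Eln (-2.37) among 3 lower. The largest negative differences were in the muscle dehydrogenase gene Dhrs7c (chromosome 10, 54352270 to 54370653), at -4.67 (-5.48 to -4.01), and in Reg3b (-3.14), Gabrb2 (-2.94), Ptn (-2.88), Rxrg (-2.86), Ntn1 (-2.82), Ddit4l2 (-2.78) and Gcgr (-2.77). Beside these groups, 5 of 10 fibroblast markers were lower, including Dpt at -2.34 and Lum at -1.82. All 9 macrophage markers (median -0.47, 1 lower) and all 8 endothelial markers (median -0.64, 0 meeting the rule) were below 0. Smooth muscle markers had 4 of 9 higher, Cnn1 by 2.67 and desmin (Des), which cardiomyocytes also express, by 1.93, and 1 lower, Mylk by -1.18. The rule was met by 919 genes, 507 higher and 412 lower; with FPKM rescaled to equal sums the split was 358 and 743.

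Both PE comparisons in vehicle use the same 0 h group, which by itself makes their differences correlate. Of the genes measured in both, 132 were higher at both times and 133 lower at both, against 13.8 and 9.52 for independent lists. Across genes the correlation was 0.56 (Pearson; genes are not independent replicates) and the covariance 0.179. In 20 simulations with no effect and a shared 0 h group, the mean correlation was 0.49, the mean covariance 0.0194 and the highest number of shared genes 1 per direction. The 0 h group could not be split, so part of the excess may come from sharing it.

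SR9009 at 0 h, after 24 h of the compound and before PE, addressed what the agonist did to unstimulated myocytes. Of 12 oxidative stress response genes 5 were higher and 0 lower, and all 12 had a difference above 0, with a median of 0.95. The metallothioneins Mt1a and Mt2A differed by 2.20 (1.72 to 2.70) and 2.11 (1.64 to 2.61), sulfiredoxin Srxn1 by 1.68 (1.29 to 2.07) and the quinone reductase Nqo1 by 1.41 (0.98 to 1.85). Among the 8 highest named genes were 3 glutathione transferases: Gsta5 (chromosome 8, 85553726 to 85564966), the highest of the named genes, had 3.29 FPKM in vehicle and 32.7 with SR9009, Gsta1 differed by 1.80 and Gstp1 by 1.67. Akr1b8 (1.88) and Reg3g (2.18) were the other 2 of the 8 largest. Members of the glutathione transferase, metallothionein and Reg3 families have close copies, and their values are uncertain where reads could be split between them.

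The mature contractile and calcium-handling list at 0 h had a median SR9009 difference of -0.55, with 17 of 18 members below 0 and 1 meeting the rule as lower, and the 10 cardiomyocyte markers had a median of -0.50, all below 0 and none meeting it. Among those lower were Lims2 (-2.23), Cd74 (-2.16), Wfdc1 (-2.07), Dhrs7c (-1.80), Efhd1 (-1.75), the α1D-adrenergic receptor Adra1d (-1.66, -2.09 to -1.23) and Cmtm5 (-1.63). Nppa, with 184 FPKM in vehicle and 181 with SR9009, and Acta1 at -0.27 did not meet the rule, nor did Nppb at 0.73 (0.31 to 1.14). Myh7 was higher by 1.19 (0.79 to 1.58), but its adjacent and near-identical neighbour Myh6 had no estimate in vehicle, so reads of the pair could be assigned differently between groups. All 9 macrophage markers were below 0, with a median of -0.74 and C1qa (-1.68) and C1qc (-1.24) meeting the rule, and Cd74, a gene of antigen-presenting cells, was lower as above. In total 111 genes met the rule, 52 higher and 59 lower.

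**Figure D2:**
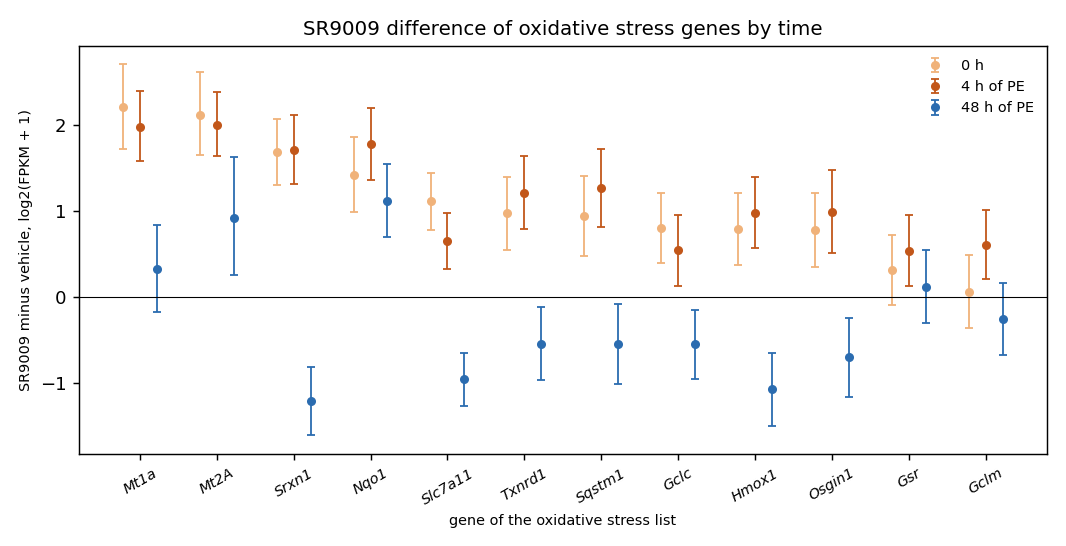
Difference of log2(FPKM + 1), SR9009 minus vehicle, for the 12 genes of the oxidative stress list at 0 h and after 4 and 48 h of phenylephrine. Points are differences of the authors' group values and bars the widest range their bounds allow; Srxn1 was at 1.68, 1.71 and -1.22.

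At 4 h of PE the SR9009 arm was compared with the vehicle arm at the same time. Of 12 oxidative stress response genes 6 were higher and 0 lower, with Mt2A at 1.99, Mt1a at 1.97, Nqo1 at 1.77 and Srxn1 at 1.71. Gsta5 differed by 3.63 (2.88 to 4.61), Gsta1 by 2.31, monoamine oxidase Maoa by 2.15, osteopontin Spp1 by 2.09 and Pla2g7 by 1.85. Rln3, with 3.79 FPKM in vehicle and 16.5 with SR9009, also differed by 1.87 (0.97 to 2.92). Of 16 hypertrophy genes 3 were lower and 0 higher, with Acta2 at -1.16, Acta1 at -1.15 (-1.55 to -0.74) and the cofactor Myocd at -1.12, and 15 of 16 were below 0. Myocd was already lower before PE, with 14.0 FPKM in vehicle and 5.67 with SR9009 at 0 h, against 32.3 and 14.3 at 4 h. Nppa at -0.70 and Nppb at -0.66 did not reach the required size. In the matrix list 4 of 23 were lower and 0 higher: Thbs1 (-1.35), Ctgf (-1.30), Eln (-1.22) and Tgfb2 (-1.17). The largest negative differences were in Ccl6 (-2.65), Cd74 (-2.37), Wfdc1 (-2.35), Adra1d (-2.34), Dhrs7c (-2.16), Hr (-1.92), Il12a (-1.88) and Tril (-1.75). The contractile and calcium-handling list had 2 of 18 genes lower and 18 below 0, with a median of -0.56, and cardiomyocyte markers had 1 of 10 lower and 9 below 0, with a median of -0.46. Macrophage markers had 3 of 9 lower and a median of -0.90, fibroblast markers a median of -0.32 with none meeting the rule, and smooth muscle markers 2 of 9 lower. The rule was met by 161 genes, 52 higher and 109 lower. The count was 255 with a pseudocount of 0.1, and the split was 61 higher and 79 lower with quantile normalization and 68 and 91 with median centring.

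At 48 h of PE the hypertrophy genes were far lower with SR9009 than with vehicle. Nppa was lower by -3.47 (-3.97 to -2.92), Nppb by -3.38 (-3.82 to -2.94), Acta1 by -2.05 (-2.49 to -1.61) and Xirp2 by -3.96 (-4.40 to -3.51), and 9 of 15 hypertrophy genes met the rule as lower, with 0 higher. Casq1 (-3.55), Scn3b (-3.50), Bdkrb2 (-3.37), the growth arrest gene Gadd45g (-2.79) and Mllt11 (-2.74, with the wide range -4.92 to -1.41) were also among the lowest. Cell cycle genes were lower in 20 of 28 cases and higher in 0, including Rrm2 at -2.48, Top2a at -2.25, Kif11 at -1.76 and Cdk1 at -1.73. Sterol and lipid synthesis genes were lower in 10 of 22 and higher in 0, with Scd1 at -2.06, Fdps at -1.46 and Idi1 at -1.43. At 4 h of PE this list went the other way with SR9009: 22 of 22 were above 0 (median 0.51), with 1 higher. Its interaction at 4 h was also above 0 in 22 of 22 (median 0.35), with 0 meeting the rule. Profibrotic and matrix genes were lower in 7 of 23 and higher in 0: the connective tissue growth factor Ctgf by -2.49, Tgfb2 by -2.43 and lysyl oxidase Lox by -1.90 are examples. Stress-response genes of the amino acid and unfolded protein list were lower in 5 of 17, with Trib3 at -1.40, Chac1 at -1.38, Atf4 at -1.29 and Dnajb9 at -1.13.

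Immediate early genes were lower in 5 of 28 cases, with Atf3 at -2.51, Myc at -2.09 and Dusp4 at -1.43, and higher in 1, Dusp5, with 9.09 FPKM in vehicle and 25.7 with SR9009. Ptgs2 (-2.04) and Lif (-1.05) were lower and Cxcl1 (1.38) higher among 13 inflammatory genes. The glycolytic genes Pfkp (-1.71) and Pfkfb3 (-1.14) were lower and Pfkm (1.07) higher. Fatty acid oxidation genes lay above 0 in 19 of 19 cases, with a median of 0.70, and 2 of them met the rule, Acaa2 at 1.26 and Cpt1a at 1.00. Hrc (1.42) and phospholamban Pln (1.03) were higher and Actc1 (-1.18) lower among 18 contractile genes. With quantile normalization Pln (0.986) and Actc1 (-0.55) no longer met the rule, nor did Lif (-0.998) and Hmox1 (-0.974) with FPKM rescaled to equal sums; Lif also missed it with median centring (-0.994). The highest differences were in Dhrs7c at 3.69 (3.03 to 4.51), Reg3b (3.14), Aldoc (2.76), Pla2g2a (2.70), Ntn1 (2.44), Rxrg (2.42), Adamtsl3 (2.32) and Ccdc85a (2.23). Of the oxidative stress list Srxn1 (-1.22) and Hmox1 (-1.08) were now lower and Nqo1 (1.12) still higher. The aryl hydrocarbon receptor targets Cyp1a1 (1.22) and Aldh3a1 (1.32) were higher out of 4 measured. Beside these, the fibroblast markers Lum (1.46) and Dcn (94.1 against 40.4 FPKM) were higher, and Cnn1 (-2.65), Acta2 (-1.50) and Des (-1.08) of 9 smooth muscle markers lower. Cardiomyocyte markers had a median of 0.26, with quartiles at -0.06 and 0.73. In total 717 genes met the rule, 243 higher and 474 lower; with FPKM rescaled to equal sums the split was 369 and 424.

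**Figure D3:**
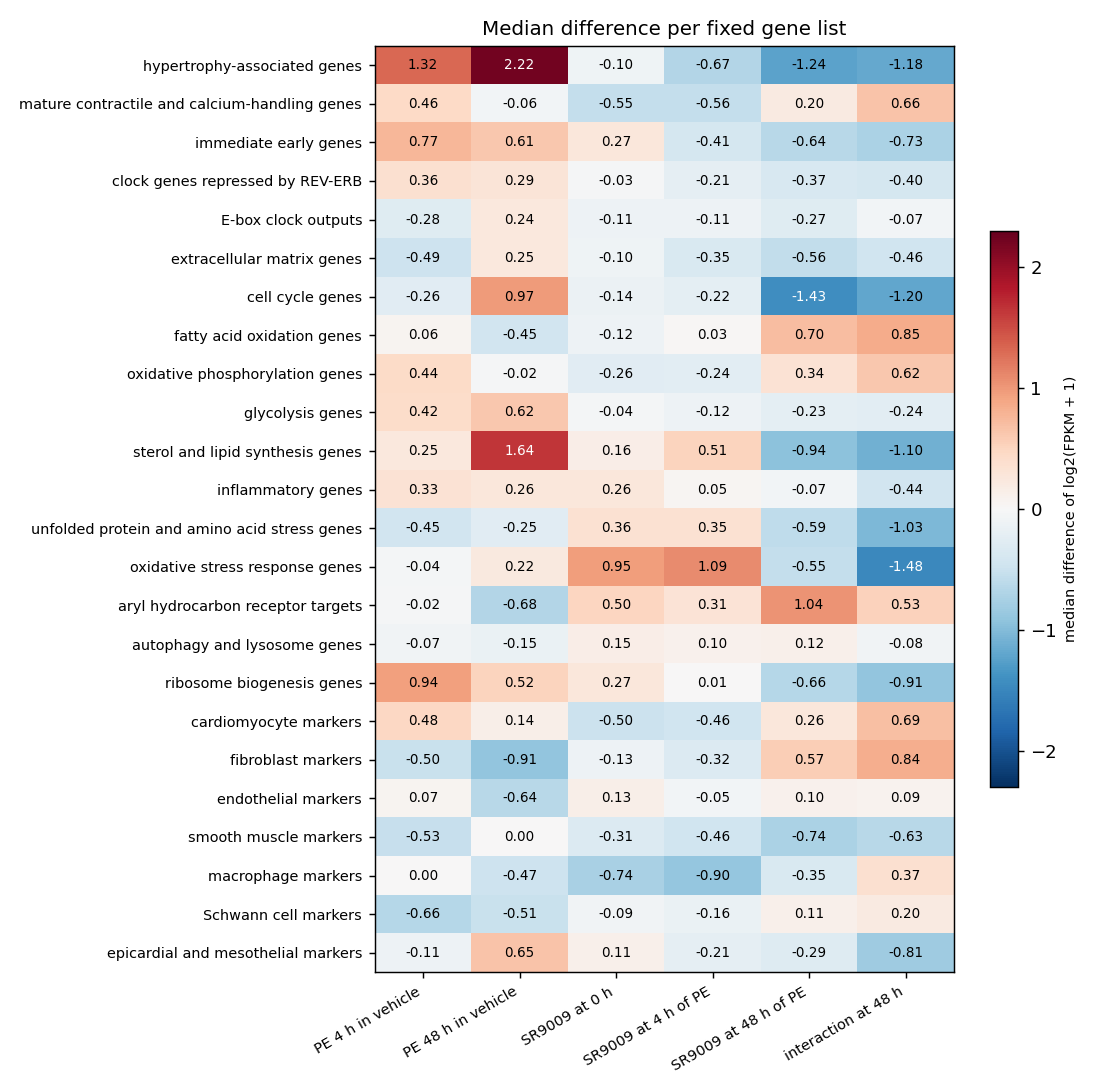
Median difference of log2(FPKM + 1) over the measured members of each fixed gene list (rows) in 6 comparisons (columns), as colour and number. The hypertrophy list was at 2.22 for 48 h of phenylephrine in vehicle and at -1.24 for SR9009 against vehicle at that time; the cell cycle list was at 0.97 and -1.43.

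The clock genes bear on REV-ERB activity, because REV-ERB represses Arntl (BMAL1) and Nfil3. At 0 h the SR9009 difference of Arntl (chromosome 1, 178039063 to 178137471) was -0.02 (-0.42 to 0.38), and none of the 5 measured REV-ERB-repressed clock genes met the rule. At 4 h of PE the difference in Arntl was -0.21 (-0.62 to 0.20). At 48 h Arntl was lower with SR9009 by -1.05 (-1.46 to -0.63) and Nfil3 by -1.09, 2 of 5 genes; Arntl fell just short of the size rule under 3 of the scalings tried, with -0.98 as the smallest difference. After 4 h of PE in vehicle, Arntl (1.30, 0.90 to 1.71) and Nfil3 (1.16) were higher than at 0 h, where PE and time in culture are not separated. Nr1d2 was lower by -0.91 at 4 h and -0.83 at 48 h of PE in vehicle, which does not reach the required size except with FPKM rescaled to equal sums (-1.11 and -1.06). Nr1d1 lay between 11.2 and 17.7 FPKM in all 6 groups, and its bounds were wide: the SR9009 difference at 0 h was -0.30 with a range of -1.41 to 0.87. The locus given for Nr1d1 (chromosome 10, 86657285 to 86690815) is wide enough to take in the neighbouring gene Thra, which overlaps it, so its values are uncertain.

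Whether the PE response itself differed between the arms was measured by the interaction. At 4 h, 44 genes met the rule, 8 higher and 36 lower. Nppb was lower by -1.39 (-2.19 to -0.58), while Nppa at -0.67 and Acta1 at -0.87 did not reach the required size. Immediate early genes were lower in 4 of 28 cases, Atf3 by -1.57, Jun and Btg2 both by -1.18 and Myc by -1.04, and 27 of 28 were below 0. The 0 h level enters these values: with SR9009 at 0 h 23 of the 28 were above 0 (median 0.27), with 1 higher. At 4 h of PE the SR9009 difference was below 0 in 25 of 28 (median -0.41), with 1 lower. Myc had 6.12 FPKM in vehicle and 15.6 with SR9009 at 0 h, and 7.20 and 8.31 at 4 h. The matrix genes Thbs1 (-1.17), Tgfb2 (-1.17) and Ctgf (-1.13) were lower. Other low values were in Ugt1a2 (-1.85), Pla2g2a (-1.59), S1pr1 (-1.55), Lgals9 (-1.42), Arl4c (-1.39) and Aldoc (-1.36). For Pla2g2a the arms differed mainly at 0 h, with 4.70 FPKM in vehicle and 14.4 with SR9009, against 9.22 and 8.17 at 4 h. Among those higher were Rln3 (1.72, a difference that the bounds no longer separated from 0 with a pseudocount of 0.1 or with FPKM rescaled to equal sums), Ccdc85a (1.24), Cxxc4 (1.15), Meis1 (1.13), Tmem179 (1.10) and Sdr39u1 (1.01). Of 438 PE-responsive genes at 4 h, 56.6% had an interaction opposed to the PE difference, 74.5% of the 208 higher ones and 40.4% of the 230 lower ones. Simulations without an effect reached from 45.8% to 56.0%, and with a pseudocount of 0.1 the observed value was 49.9%. The median PE difference of the higher genes was 1.502 in vehicle and 1.233 with SR9009, and that of the lower genes -1.188 and -1.254.

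At 48 h the interaction met the rule for 941 genes, 386 higher and 555 lower (541 and 465 with FPKM rescaled to equal sums). Bdkrb2 was lowest at -4.53, followed by Nppb at -4.11 (-4.96 to -3.26), Xirp2 at -3.77, Scn3b at -3.62, Nppa at -3.44 (-4.34 to -2.50), Myc at -3.31, and Atf3 and Tmeff1 at -2.92. Hypertrophy genes were lower in 8 of 15 cases, cell cycle genes in 18 of 28 (Rrm2 at -2.40), sterol and lipid genes in 12 of 22 (Scd1 at -2.46) and immediate early genes in 10 of 28, with 1 higher. The oxidative stress list had 9 of 12 lower and 0 higher, and the unfolded protein and amino acid stress list 8 of 17 lower and 0 higher, with Trib3 at -2.43. Both lists lay above 0 with SR9009 at 0 h, in 12 of 12 (median 0.95) and 17 of 17 genes (median 0.36), and this enters their interactions. Trib3 had 34.5 FPKM in vehicle and 71.7 with SR9009 at 0 h. Dhrs7c was highest at 5.49 (4.38 to 6.76), then Cd74 (3.47), Rxrg (3.37), Smim5 (2.93), the natriuretic peptide convertase Corin (2.88), Ccdc85a (2.87), the fatty acid oxidation enzyme Hadh (2.86) and Ppap2b (2.82). Contractile and calcium-handling genes were higher in 8 of 18 cases and lower in 0, including Hrc (2.42), the ryanodine receptor Ryr2 (1.83), Atp2a2 (1.68) and Tnni3 (1.25). The lower 0 h level with SR9009 (list median -0.55) enters these interactions. The SR9009 difference of the list at 48 h itself had a median of 0.20, with 2 higher and 1 lower. Fatty acid oxidation genes were higher in 4 of 19, among them Acaa2 (1.39), the coactivator Ppargc1a (1.19) and Ppara (1.09), and lower in 0. Fibroblast markers were higher in 5 of 10 and cardiomyocyte markers in 4 of 10, with 0 lower in either.

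Of 321 PE-responsive genes at 48 h, 80.4% had an interaction opposed to the PE difference, 84.5% of the 193 higher genes and 74.2% of the 128 lower ones. Simulations without an effect reached from 47.9% to 57.8%. The median PE difference of the higher genes was 1.87 in vehicle and 0.84 with SR9009, and that of the lower genes -1.62 and -0.92. The percent depends on how the genes are selected: it was 97.4% when they were selected in the vehicle arm, which favours opposition, and 25.9% when selected in the SR9009 arm, which works against it.

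**Figure D4:**
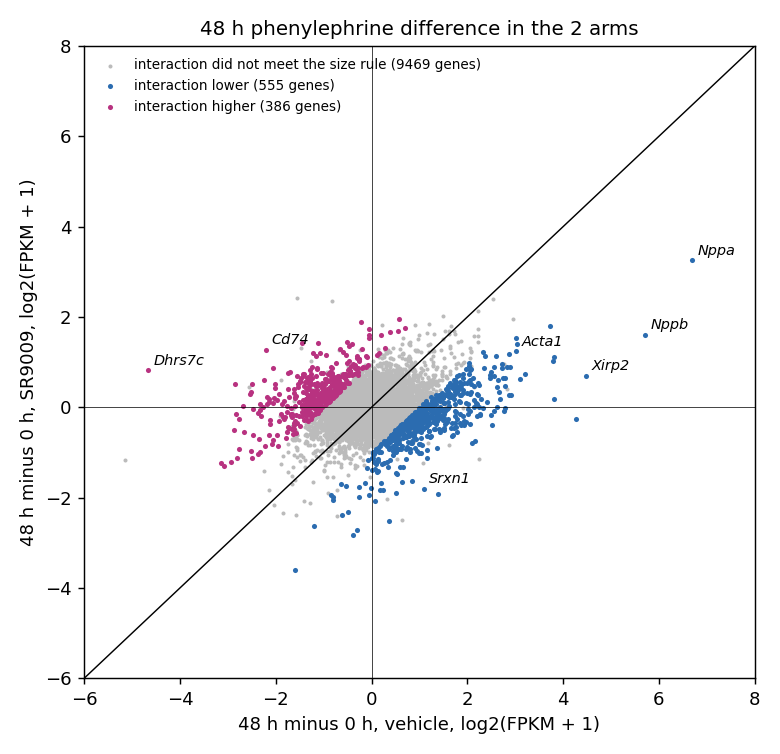
Difference of log2(FPKM + 1) between 48 h and 0 h of phenylephrine in the vehicle arm (x axis) and the SR9009 arm (y axis), 1 point per gene, with the line of equal differences. Coloured genes met the size rule for the interaction, 555 lower and 386 higher; Nppa lies at 6.69 in vehicle and stays below the line.

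Within the SR9009 arm, 466 genes met the rule after 4 h of PE, 190 higher and 276 lower, and 252 after 48 h, 131 higher and 121 lower. With FPKM rescaled to equal sums the splits were 161 and 486, and 113 and 184. For 4 h, quantile normalization gave 211 higher and 206 lower, and median centring 224 and 230. At 4 h, 149 genes were higher in both arms and 141 lower in both, against 5.10 and 6.32 for independent lists. At 48 h, 55 were higher and 33 lower in both, against 6.37 and 4.73, while 506 were higher and 410 lower in vehicle. At 48 h with SR9009 the hypertrophy list still had 6 of 15 genes higher and 0 lower, and Nppa rested at 1734 FPKM against 181 at 0 h. Cell cycle genes had 0 of 28 meeting the rule, and sterol genes 1 of 22. Contractile genes were higher in 7 of 18 cases and cardiomyocyte markers in 5 of 10, with 0 lower in either. The unfolded protein and amino acid stress list had 10 of 17 lower and the oxidative stress list 7 of 12 lower, with 0 higher in either.

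The SR9009 differences at the 3 times share no group. Across 10410 genes, those at 0 h and at 4 h of PE correlated at 0.59 (Pearson) and 0.52 (Spearman), with 18 genes higher and 23 lower at both times against 0.245 and 0.559 for independent lists. Between 0 h and 48 h the correlations were -0.08 and -0.13, with 8 genes higher and 8 lower at both times (1.08 and 2.54 for independent lists) and 12 in opposite directions. Between 4 h and 48 h they were 0.05 and 0.03, with 4 higher and 29 lower at both (1.14 and 4.78) and 15 in opposite directions. Oxidative phosphorylation genes had none of 20 meeting the rule at any time, with medians of -0.26, -0.24 and 0.34. The autophagy and lysosome list had medians of 0.15, 0.10 and 0.12, with Pink1 the single member of 20 to meet the rule, at 1.78 at 48 h. Endothelial markers had medians of 0.13, -0.05 and 0.10, Schwann cell markers -0.09, -0.16 and 0.11, and epicardial and mesothelial markers 0.11, -0.21 and -0.29, with none meeting the rule.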

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

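The tests of scaling and of reads from other cells for the weaker PE response, and both tests for the oxidative stress genes, were chosen only after the result was seen; the test of fewer cardiomyocytes was written before. With 1 value per gene and group, no difference between the arms was tested.

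At 48 h of PE 10 genes met the size rule in opposite directions in the vehicle and SR9009 arms. Of the 10410 genes measured in both, 506 were higher and 410 lower in vehicle, and 131 and 120 with SR9009. The opposite calls that independent lists of these sizes would share were not computed, so 10 is not shown to be an excess. Of the 10, 4 were higher with PE in vehicle and lower with PE in the SR9009 arm, with interactions of -3.31 for Myc, -2.89 for Srxn1, -2.27 for Gdf15 and -2.04 for Tbkbp1. The reverse held for 6, with interactions of 3.47 for Cd74, 2.88 for Corin, 2.54 for Ckmt2, 2.42 for Hrc, 2.29 for Rab6b and 2.28 for Pgam2. With SR9009 at 0 h the 4 lay above vehicle, from 0.46 (Tbkbp1) to 1.68 (Srxn1). The 6 lay below it, from -0.67 (Corin) to -2.16 (Cd74). These 0 h differences enter the interactions. At 48 h the 4 lay below vehicle, from -1.22 (Srxn1) to -2.09 (Myc). The 6 then lay above it, from 1.25 (Ckmt2) to 2.21 (Corin). Srxn1 had 15.4 FPKM in vehicle and 51.5 with SR9009 at 0 h, and 34.0 and 14.1 at 48 h. Between 0 h and 48 h the SR9009 difference had opposite directions in 12 genes, between 4 h and 48 h in 15, and 3 genes, Cd74, Ckmt2 and Srxn1, belong to all of these sets.

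The PE response at 48 h was smaller in the SR9009 arm, with 80.4% of PE-responsive genes opposed. A scaling difference of the SR9009 group would leave PE-higher or PE-lower genes mostly unopposed, yet the lower of the percents in the 2 directions was 74.2. Fewer cardiomyocytes would lower their markers about as much as the 193 PE-higher genes, whose median SR9009 difference was -1.18. The lower quartile of the markers was -0.062. This cannot settle the number of cells, because the markers themselves changed between 0 h and 48 h. Their median difference from 0 h was 0.14 in vehicle and 1.02 in the SR9009 arm, with a median interaction of 0.69. With SR9009 at 0 h all 10 were below 0 (median -0.50). Reads from other cells stay open: the highest interaction among Nppa, Nppb, Acta1 and Xirp2 was -1.78, but 3 of these 4 are among the pattern's 8 lowest named genes, so the test decides nothing. A reduced hypertrophic response with SR9009 is a hypothesis beside fewer cardiomyocytes and reads from other cells, and it was not tested. Whether the response is to PE or to time in culture stays open too, as does variation between cultures beyond the authors' bounds.

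The oxidative stress list had a median interaction of -1.48 at 48 h: its median SR9009 difference was 0.95 at 0 h and -0.55 at 48 h. At 48 h 8 of 12 genes were below 0 and 4 above, and Nqo1 was still higher. The metallothioneins also stayed above vehicle, Mt2A at 64.7 FPKM with SR9009 against 33.8 and Mt1a at 107 against 85.2. Outside the list, Gsta1 had 19.2 FPKM with SR9009 against 7.15 in vehicle at 48 h, and Gstp1 283 against 184. Reads shared between close copies could raise the glutathione transferases and metallothioneins at 0 h. The 10 list members outside these families had a median of 0.87 and a lower quartile of 0.77. Reads shared within these families therefore do not account for the values of those 10 members. For the glutathione transferases and metallothioneins themselves the question stays open, because the test left them out. A scaling difference at 0 h would move other genes alike, and the median of all genes was -0.015. No biological explanation of the values at 48 h was tested, and a loss of the 0 h difference alone would bring the list to about 0, not below it.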

How the results depend on the processing

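The 1.5-fold size rule, the size rule without bounds, the removal of small and ribosomal RNA genes and the rescaling to equal sums were tests chosen only after the result was seen. Of the counts of genes, 71 stayed within 1.5 times under the alternatives. With the 1.5-fold rule, 1768 genes met it for 4 h of PE and 2259 for 48 h in vehicle, 1712 and 1042 with SR9009, 483, 745 and 1914 for SR9009 at 0, 4 and 48 h, and 81 for the interaction at 4 h; a lower size admits more genes by construction. The count for SR9009 at 4 h was 255 with a pseudocount of 0.1, and that for the interaction at 4 h was 84 without the bounds. The percent opposed at 4 h was 49.9 with a pseudocount of 0.1 (the cause was not tested), 76.0 with selection in the vehicle arm, 35.6 in the SR9009 arm and 51.8 with no minimum size; at 48 h these selections gave 97.4, 25.9 and 73.8, and selection in 1 arm is biased by construction. The correlations between the SR9009 differences at the 3 times kept their side in all 21 repeats. For the 216 list medians, 1372 repeats stayed the same, 130 moved and 1 reversed, the macrophage markers for 4 h of PE with SR9009, at 0.059 with quantile normalization against -0.22; the cause was not tested. Among named genes 2028 repeats were the same, 21 lost the size rule, 2 gained it (Nr1d2 at 4 and 48 h) and 0 reversed. No paired analysis was possible because the table holds 1 value per group and no replicate. For the same reason the planned limma settings, library weights, replicate block, adjusted p threshold, leaving out of libraries, camera, fry and other splits of the samples were not run. Depth is unknown, so its limit on low genes could not be given.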

Other observations

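The interferon, α1-adrenergic receptor, skeletal muscle and atrial gene lists here, and the tests of clock genes, of receptors and of scaling for the macrophage genes, were chosen only after the result was seen; the test of fewer macrophages was written before. Interferon-stimulated genes were higher after PE in vehicle: 6 of 21 at 4 h and 11 of 21 at 48 h, with 0 lower. Isg15 had 8.95 FPKM at 0 h, 28.4 at 4 h and 71.3 at 48 h, and Mx2 had 5.97, 12.3 and 18.6. With SR9009 at 48 h, 7 of the 21 were lower than in vehicle and 0 higher, with Isg15 at 13.4 FPKM, and 10 had a lower interaction. At 0 h SR9009 went with 1 higher member, Ifi27l2b, at 268 against 90.6 FPKM.

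Of 9 measured skeletal muscle isoform genes, 4 were higher and 1 lower after 48 h of PE in vehicle. Casq1 had 22.1 FPKM at 0 h and 321 at 48 h, and the myosin light chain Myl1 7.09 and 56.5, while the muscle creatine kinase Ckm, which heart also expresses, had 665 and 327. With SR9009 at 48 h, 5 were lower and 1 higher than in vehicle. The 5 measured atrial isoform genes were split, with 1 higher and 3 lower after 48 h of PE in vehicle. Myl4 had 137 FPKM at 0 h and 781 at 48 h, while Myl7 had 189 and 91.8 and the connexin gene Gja5 23.1 and 6.95. With SR9009 at 48 h 1 was higher, Gja5 at 31.1 FPKM, and 1 lower, Myl4 at 136 FPKM.

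All 9 macrophage markers were below 0 with SR9009 at 0 h. Fewer macrophages would lower them alike. The upper quartile of their differences was -0.70, with 0 of 9 at or above 0 and 0 on another of the fixed lists. This test asks for a shared direction and not for equal size. The lower quartile was -0.83, but the sizes were uneven beyond it: C1qa and C1qc, 2 of 9, met the size rule. Lyz2 had 17.5 FPKM in vehicle and 12.1 with SR9009, Tyrobp 10.9 and 5.70, and Csf1r 2.96 and 1.35. The median of all genes was -0.015, which argues against scaling. An upper quartile below 0 was not particular to these markers: that of the 10 cardiomyocyte markers was -0.32 at 0 h. A smaller share of macrophages may account for the macrophage genes at 0 h. The test cannot tell it from lower transcription per macrophage, which stays open.

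At 48 h of PE the median SR9009 difference of the macrophage markers was -0.35, with 7 of 9 below 0 and 1 lower, and their median interaction was 0.37, with 8 of 9 above 0. Cd74, lower with SR9009 at 0 h, was then higher, with 9.77 FPKM against 3.34 in vehicle.

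A hypothesis that 24 h of SR9009 lowers the clock genes that REV-ERB represses was tested at 0 h. The median difference of the 5 measured genes was -0.028, with quartiles at -0.16 and -0.02, so no such lowering was seen before PE. Protein levels and circadian phase were not analysed here.

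A hypothesis that fewer α1-adrenergic receptors reduce the whole PE response was also tested. The FPKM of the 3 receptor genes summed to 88.4 in vehicle and 44.0 with SR9009 at 0 h, with Adra1d meeting the size rule. Adra1d had 36.3 and 10.8 FPKM, Adra1b 39.5 and 23.3, and Adra1a 12.6 and 9.86. A weaker signal would shrink both directions of the response. At 4 h the median PE difference of PE-lower genes with SR9009 was 1.06 times that of vehicle, against 0.82 times for PE-higher genes. Genes that follow time in culture would not shrink with the signal. No culture without PE separates them, so the values at 4 h do not decide the question. At 48 h the ratios were 0.56 and 0.45, while 2 of the 3 receptor genes were lower in vehicle itself after PE. With SR9009 at 48 h 1 of the 3 was higher than in vehicle, Adra1b at 21.1 against 6.87 FPKM, and 0 were lower.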
